A study of Homo sapiens with 4 samples.

How the data were processed

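RNA was measured in 4 libraries from NB4, an established human leukaemia cell line that is widely used as a model of acute promyelocytic leukaemia and that the labels describe as acute monocytic leukaemia. Cells carried a lentiviral short hairpin vector, pLKO.1, with either a control hairpin (shNS) or a hairpin against FTO (shFTO), and 2 libraries were labelled for each. Per the labels' protocols and the series' design text, infected cells were selected with puromycin at 1 ug/ml at 72 hours after infection, polyA RNA was isolated, and directional libraries were made with a NEBNext kit. Cells were harvested after 2 generations of selection. The labels do not say whether the 2 libraries of a group came from separate infections or cultures, so p-values measure only the spread between these samples, which may be technical.

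Expected counts, which need not be whole numbers, were estimated per gene by the authors with RSEM 1.2.31 on GRCh38, per the submitters' processing notes. Each deposited table had 26830 rows, and no row listed more than 1 RefSeq transcript. A change in which transcript of a gene is used could therefore appear as a change in the level of that gene. TPM and FPKM values were deposited by the authors beside the counts. TPM values, scaled by RSEM for transcript length and depth per the file headers, entered 1 alternative, and FPKM values were not used. The deposited transcript lengths served only for a check of length trends. The aligner, read trimming and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes may not be told apart.

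Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 15554 genes. Libraries were scaled by TMM, and shFTO was compared with shNS by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, limma 3.58.1, R 4.3.3) with group as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are TMM-normalised counts scaled to library size (CPM), given as mean ± SD with n = 2 per group. Where both libraries of a group held 0 counts, a fold was computed against a floor of 3 counts per library, averaged over the group's libraries on the CPM scale. Floors cover counting error only.

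Before the data were examined, 25 gene lists were fixed. Of their symbols, 715 matched the deposited symbols, 44 were matched through RefSeq accessions and 30 had no matching row and are not analysed here. The mitochondrially encoded list was among these, which left 24 lists for camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry. Camera with an estimated correlation takes its p-value from the residual degrees of freedom of the fit, 2 here, so it has little power. Counts of list members given below are of members that passed the count filter, which keeps genes high in either group alone. The genes to be named were also set by rule beforehand. They were FTO, the genes linked to it in earlier work, and the 12 highest and 12 lowest genes that passed the test, had a mean of at least 5 CPM and had groups that did not overlap. From each list, up to 3 passing members in each direction followed. Some genes that the rule names are not reported here. A further 6 lists were written after the largest changes had been seen and appear only in the closing section. Coordinates come from the GENCODE release 29 annotation of GRCh38.

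The test was checked on simulated counts drawn from these libraries' means, sizes and fitted dispersions, with 50 genes changed at each size. It recovered 44% of genes changed 1.25-fold, 82% of those changed 1.5-fold, 80% of those changed 2-fold and 92% of those changed 4-fold, and called 14 unchanged genes. After filtering, 15343 simulated genes were tested. Far fewer genes changed than were called in the data, and rises and falls were balanced. Error from cultures that libraries may share was not simulated.

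Alternatives covered other scalings (DESeq2 size factors, upper quartile, library size only), other tests (the DESeq2 1.42.0 Wald test and limma-voom), no filter and a filter of 1 CPM in 2 libraries. They also covered the deposited TPM values as log2(TPM + 1) in limma-trend, a replicate block, each library left out in turn, a threshold of 0.01 and a test against a 1.5-fold change. Removal of 4 ribosomal RNA rows, removal of each library's trend with GC content and length, a robust fit and the FTO-linked list without FTO were added after the data were seen.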

Results

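The data were 4 polyA RNA libraries of NB4 leukaemia cells, 2 from cells with the control hairpin shNS and 2 from cells with the FTO hairpin shFTO. Total expected counts were 29555274 and 31709942 in the shNS libraries and 25056703 and 23937480 in the shFTO libraries, so that 3 counts corresponded to between 0.0984 and 0.125 CPM. Ribosomal RNA rows took 4.99% and 7.11% of counts in shNS and 3.56% and 3.98% in shFTO. Across genes, log2 CPM values correlated at r = 0.992 between the shNS libraries and r = 0.991 between the shFTO libraries, against 0.948 to 0.951 between groups, although genes are not independent replicates. The first principal component held 85.4% of the variance and separated the groups.

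FTO, which encodes an RNA demethylase that removes m6A marks, was the target of the knockdown and was lower in both shFTO libraries. FTO (NM_001080432; GRCh38 chromosome 16, 53701692 to 54158512, plus strand) stood at 50.5 and 47.4 CPM in the shNS libraries and 19.9 and 19.2 CPM in the shFTO libraries. Its log2 fold change was -1.32 ± 0.07 (SE), with an edgeR quasi-likelihood adjusted p of 7.6e-09. IRX3 and IRX5, homeobox genes on the same chromosome, also fell, by 0.86 ± 0.06 and 1.18 ± 0.11 on the log2 scale. MYC, a transcription factor that drives cell growth, fell from 877 ± 1.34 to 518 ± 5.34 CPM (log2 fold change -0.76). LDHB, a lactate dehydrogenase subunit, fell by 0.43 ± 0.08 on the log2 scale. ASB2 and CEBPA, which act in myeloid differentiation, rose by 1.18 ± 0.21 and 0.54 ± 0.06. RARA, the retinoic acid receptor, had a log2 fold change of -0.07 (adjusted p 0.47), RPGRIP1L one of -0.21 (adjusted p 0.16) and PFKP one of 0.16 (adjusted p 0.056). Of the 10 measured genes of this list, 2 rose and 5 fell by edgeR (3 and 5 adjusted over the list alone). Camera gave an adjusted p of 0.028, or adjusted p = 0.27 with an estimated correlation, but the list holds the knockdown's own target. Without FTO the other 9 genes had a median log2 fold change of -0.21 and did not pass (camera adjusted p 0.11, and adjusted p = 0.37 with an estimated correlation).

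**Figure D1:**
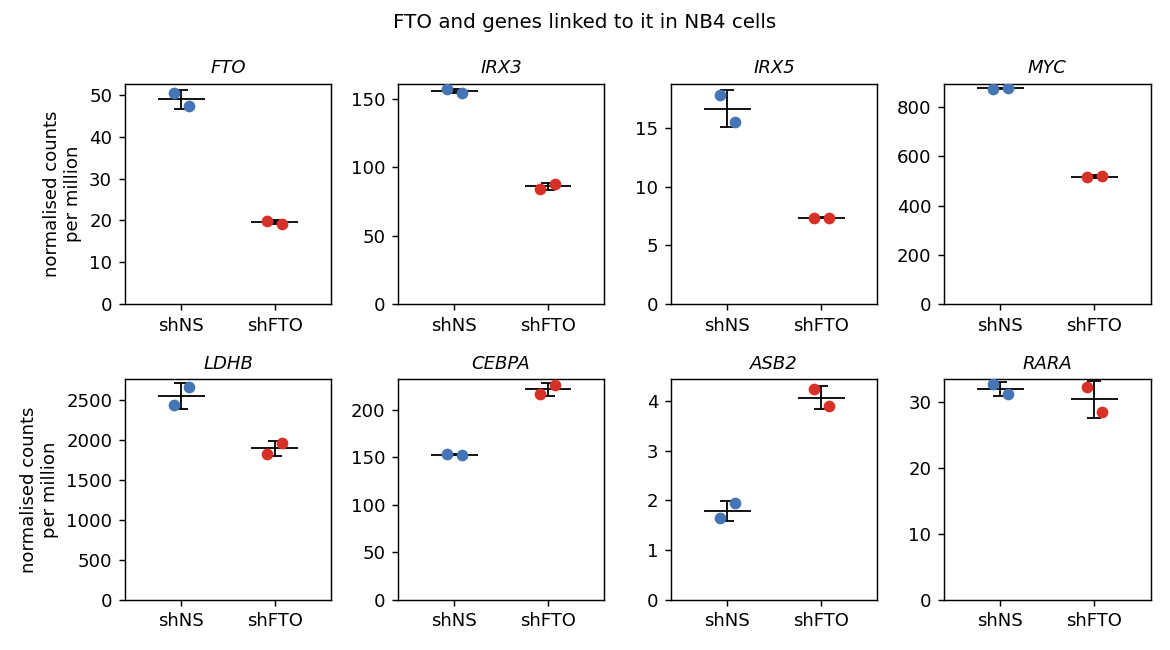
Normalised CPM (vertical axes, each from 0) of FTO and genes linked to it in the shNS and shFTO libraries. Points are libraries, horizontal lines are means and bars are SD (n = 2); FTO fell from 48.9 to 19.5 CPM, and the RARA groups overlapped.

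The comparison of shFTO with shNS asked which transcripts differ in NB4 cells when FTO is knocked down. Of the lists fixed beforehand, monocyte and macrophage genes and interferon-stimulated genes had the highest median log2 fold changes, 3.03 and 2.77 (adjusted p = 0.069 and 0.056 with an estimated correlation). PSAT1 and ASNS, of serine and asparagine synthesis, were among the 12 lowest genes. By the edgeR quasi-likelihood test, 4421 genes were higher and 4082 lower among 15554 tested. The rises were larger than the falls. At least 2-fold changes numbered 1889 higher and 308 lower, at least 4-fold changes 753 and 43, and the median absolute log2 change was 0.84 among higher and 0.43 among lower genes. On the deposited TPM values, 62.5% of called genes were higher, against 52.0% here, with 4416 higher and 2655 lower. Of the 8503 calls, 78.0% still passed on TPM, 83.4% by the DESeq2 Wald test and 91.6% with library size only. Other scalings, filters and corrections with all 4 libraries kept at least 94.6%.

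The 12 genes with the highest fold changes by the naming rule were CCL8, SIGLEC1, GPNMB, CD36, C1QC, SLCO2B1, OLFML2B, FPR3, EMP1, IL1B, OAS2 and MPEG1. CCL8, a chemokine, had 0 counts in both shNS libraries and 12.2 ± 1.35 CPM in shFTO, at least 122-fold higher against the floor. SIGLEC1, a macrophage sialic acid receptor, rose from 0.132 ± 0.0915 to 40.9 ± 2.41 CPM. The scavenger receptor CD36 rose from 0.248 ± 0.113 to 45.4 ± 1.92 CPM and GPNMB, a glycoprotein of macrophages and lysosomes, from 0.367 ± 0.148 to 86.4 ± 2.27 CPM. IL1B, an inflammatory cytokine, rose from 1.19 ± 0.26 to 81.3 ± 2.82 CPM. The lowest 12 were ELFN1, STMN3, PSAT1, ASNS, ALDH1L2, SCLY, AES, TRMT112, LSP1, GTF2F2, EPN1 and JDP2. PSAT1, an enzyme of serine synthesis, fell from 207 ± 3.42 to 35.2 ± 1.15 CPM, and ASNS, which makes asparagine, from 176 ± 0.60 to 31.3 ± 0.91 CPM. ELFN1 fell from 18 ± 1.49 to 1.42 ± 0.36 CPM. All 24 had both shFTO libraries on the same side of both shNS libraries, as the naming rule required.

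**Figure D2:**
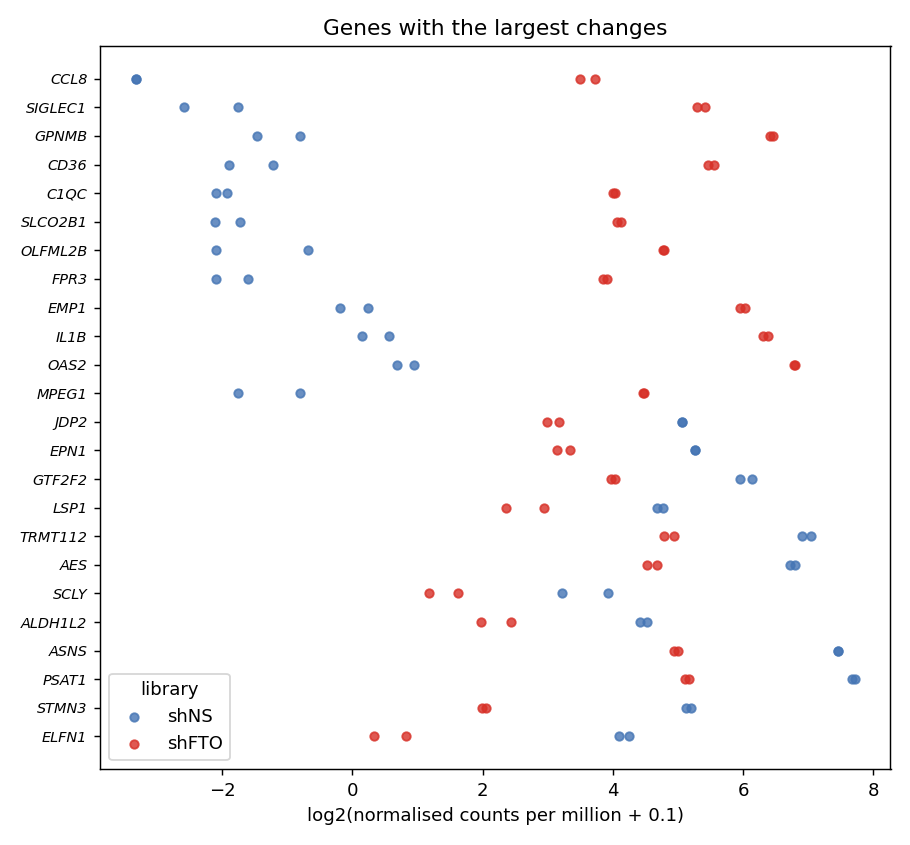
Levels of the 12 highest and 12 lowest genes in each library, on a horizontal log2 axis of normalised CPM with a small constant added so that 0 can be drawn. Each point is a library; in every row the shNS and shFTO points are apart, as the rule for these genes required, and CCL8 lies at 0 CPM in both shNS libraries.

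Monocyte and macrophage genes rose together in shFTO. Of 32 measured members, 30 rose and 1 fell (31 and 1 adjusted over the list alone), with a median log2 fold change of 3.03. Besides SIGLEC1 and CD36, the scavenger receptor MARCO reached 5.99 ± 0.51 CPM from 0.0656 ± 0.0928 CPM. FCGR1A, an Fc receptor, was the member that fell, from 28.3 ± 0.43 to 20.8 ± 2.90 CPM. Camera gave an adjusted p of 1.6e-53, or adjusted p = 0.069 with an estimated correlation.

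Interferon-stimulated genes showed the same direction, with 39 of 41 measured members rising and 0 falling (39 and 0 adjusted over the list alone) and a median log2 fold change of 2.77. OAS2 rose from 1.68 ± 0.23 to 110.6 ± 0.71 CPM, OAS3 from 7.52 ± 0.42 to 433 ± 15.3 CPM and IFI27 from 0.581 ± 0.0596 to 37.9 ± 1.05 CPM. Camera gave an adjusted p of 1e-94, or adjusted p = 0.056 with an estimated correlation. Among 32 NF-kB targets and cytokines, 25 rose and 2 fell (25 and 2 adjusted over the list alone). The chemokine CCL2 rose from 1.49 ± 0.44 to 63.0 ± 3.84 CPM, while NFKB2 and NFKB1 fell by 0.40 and 0.23 on the log2 scale. The NF-kB list had a camera adjusted p of 1.2e-15, or adjusted p = 0.26 with an estimated correlation.

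Granule and granulocyte genes also rose. In the primary granule list of 18 genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 1.21. The 11 members not shared with monocytes, a set chosen after the data were seen, had a lower median of 0.52, with 8 rising and 1 falling. Lysozyme (LYZ) rose from 64.8 ± 0.40 to 896 ± 47.9 CPM, the granule proteoglycan SRGN from 732 ± 37.4 to 5477 ± 213 CPM and NKG7 from 19.0 ± 2.11 to 130.1 ± 8.94 CPM, while the defensin DEFA4 fell from 5.65 ± 0.08 to 1.59 ± 0.28 CPM. The primary granule list's camera adjusted p was 4.6e-17, or adjusted p = 0.26 with an estimated correlation. Of 33 genes of later granulocyte maturation with a row, only 19 passed the count filter, which keeps genes high in either group alone. Of these 19, 15 rose and 1 fell (15 and 1 adjusted over the list alone). Their median was 2.42, or 1.42 without shFTO replicate 2 and 0.96 with no filter on low counts. FPR2 and FPR1, receptors for formyl peptides, reached 3.04 ± 0.40 and 1.26 ± 0.02 CPM from levels under the floor. MMP8 reached 0.669 ± 0.29 CPM from 0 counts, and CSF3R fell by 0.23 on the log2 scale. This list had a camera adjusted p of 4.6e-12, or adjusted p = 0.098 with an estimated correlation. Genes known to respond to retinoic acid followed, with 24 of 32 rising and 1 falling (24 and 1 adjusted over the list alone) and a median of 1.3. The chemokine CCL2, also on this list, rose as given above, while CYP26B1 fell by 1.09 on the log2 scale. The retinoid list's camera adjusted p was 4.3e-22, or adjusted p = 0.098 with an estimated correlation, and 13 of its genes stood on other lists.

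Growth genes moved the other way. Among 40 MYC targets, 34 fell and 2 rose (35 and 3 adjusted over the list alone), with a median log2 fold change of -0.56. DDX21, a helicase of ribosome production, fell from 905 ± 24.8 to 459 ± 11.7 CPM, and RRP9 and RRP12 fell by 1.06 and 0.98 on the log2 scale. LDHA, lactate dehydrogenase A, rose from 316 ± 14.2 to 656 ± 21.8 CPM. Camera's adjusted p was 1.3e-09, or adjusted p = 0.26 with an estimated correlation. Of 57 ribosomal protein genes, 53 fell and 0 rose (53 and 0 adjusted over the list alone), and RPL5 fell from 1767 ± 169 to 984 ± 73.0 CPM. The ribosomal list's camera adjusted p was 2.4e-07, or adjusted p = 0.54 with an estimated correlation. Processed pseudogenes share reads with many of these genes, so single values carry that uncertainty.

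DNA replication genes fell in 35 of 46 cases and rose in 4 (35 and 4 adjusted over the list alone), with a median of -0.40. CDT1, which licenses replication origins, fell from 283 ± 8.05 to 127 ± 4.69 CPM and the helicase subunit MCM3 from 513 ± 2.60 to 273 ± 4.53 CPM, while TK1 and RRM2 rose by 0.74 and 0.56 on the log2 scale. Camera's adjusted p was 1.3e-06, or adjusted p = 0.13 with an estimated correlation. Of 46 mitotic genes, 29 fell and 5 rose (31 and 5 adjusted over the list alone). MAD2L1 and BUB1B, of the spindle checkpoint, fell by 0.71 and 0.60, and PRC1 and KIF20A rose by 0.45 and 0.45. The mitotic list had a camera adjusted p of 0.0019, or adjusted p = 0.26 with an estimated correlation. Replication-dependent histones lack a polyA tail and stood at low levels. In that list 14 of 27 fell and 1 rose (14 and 1 adjusted over the list alone), and HIST1H1E fell from 6.0 ± 1.77 to 1.47 ± 0.10 CPM. The histone list's camera adjusted p was 0.024, or adjusted p = 0.54 with an estimated correlation, and 0.065 without shNS replicate 2 and 0.094 with the GC and length trend removed.

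Metabolic and cell death lists were also measured. Among 24 BCL2 family and caspase genes, 16 rose and 3 fell (16 and 4 adjusted over the list alone). BCL2A1 rose from 0.582 ± 0.0125 to 6.78 ± 0.58 CPM, and the survival factor BCL2 fell from 105 ± 5.98 to 62.0 ± 0.25 CPM. Camera's adjusted p was 0.017, or adjusted p = 0.26 with an estimated correlation. Of 40 nuclear respiratory chain genes, 19 fell and 3 rose (19 and 3 adjusted over the list alone), with COX6A1 falling by 0.78 and NDUFA4 rising by 0.42 on the log2 scale. The respiratory list's camera adjusted p was 0.014, or adjusted p = 0.65 with an estimated correlation, and 0.053 without shNS replicate 2, 0.056 without shFTO replicate 1 and 0.059 with the GC and length trend removed. Of 35 glycolysis and hypoxia genes, 14 rose and 7 fell (15 and 8 adjusted over the list alone). HK1 rose from 7.09 ± 0.83 to 35.2 ± 1.52 CPM and VEGFA fell from 95.8 ± 1.64 to 40.7 ± 1.34 CPM. The glycolysis list's camera adjusted p was 0.028, or adjusted p = 0.37 with an estimated correlation, and its median was 0.09. Camera's adjusted p for it was 0.095 with no filter on low counts and 0.13 with the replicate block.

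The remaining lists did not pass camera, apart from the lymphoid one. Of 24 genes that write, erase or read m6A, 15 fell and 4 rose (16 and 5 adjusted over the list alone), with a camera adjusted p of 0.067 and a call in 3 of 13 alternative settings. IGF2BP1 and HNRNPC fell by 0.68 and 0.53 on the log2 scale, and IGF2BP3 rose by 0.86. Of 26 p53 targets, 13 rose and 7 fell (14 and 7 adjusted over the list alone, camera adjusted p 0.23). The cell cycle inhibitor CDKN1A rose from 7.37 ± 1.18 to 37.4 ± 0.55 CPM and XPC fell by 1.31 on the log2 scale. Of 24 stem and progenitor genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p 0.13), with EVI2B rising by 2.47 and HGF falling by 1.04. The ATF4 and unfolded protein list was split, with 14 of 33 rising and 13 falling (15 and 13 adjusted over the list alone). Its endoplasmic reticulum chaperone HSPA5 rose from 455 ± 12.3 to 1154 ± 21.8 CPM, as did MANF and SDF2L1, each by 1.38 on the log2 scale. PSAT1, ASNS and PHGDH, which make serine and asparagine, fell. The median of this list was 0.14 and its mean -0.08, and camera pointed down with an adjusted p of 0.21. Camera pointed up for this list with no filter (adjusted p 0.94) and with the replicate block (adjusted p 0.87). Of 31 sterol and fatty acid genes, 16 fell and 6 rose (16 and 6 adjusted over the list alone, camera adjusted p 0.093, with a call in 2 of 13 alternative settings), with ELOVL6 rising by 1.08 and IDI1 falling by 0.74 on the log2 scale. Of 23 immediate-early and heat shock genes, 13 rose and 8 fell (13 and 8 adjusted over the list alone, camera adjusted p 0.71), with KLF6 rising by 1.74 and EGR1 falling by 1.32.

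Markers of other cell types were measured beside these groups. Of 11 lymphoid markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.0078, or adjusted p = 0.26 with an estimated correlation, and 0.20 without shNS replicate 1 and 0.11 with no filter. CD4, which monocytes also express, rose from 49.6 ± 3.0 to 247 ± 7.87 CPM. Of 22 erythroid and megakaryocyte markers, 11 passed the count filter. Of these 11, 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p 0.067, with a call in 1 of 13 alternative settings). ITGA2B rose from 6.72 ± 0.46 to 51.4 ± 1.36 CPM. HBA2 fell from 2.45 ± 2.42 to 0.0623 ± 0.0881 CPM, with an SD near its mean in shNS. Of 21 markers of adherent and packaging cells, 12 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p 0.067), and TPM1 rose by 2.41 ± 0.20 on the log2 scale. This list passed camera in 5 of 13 alternative settings, with the lowest adjusted p, 0.0046, with no filter. With an estimated correlation, which has little power here, it passed in 0 of them, and its adjusted p with no filter was 0.43.

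**Figure D3:**
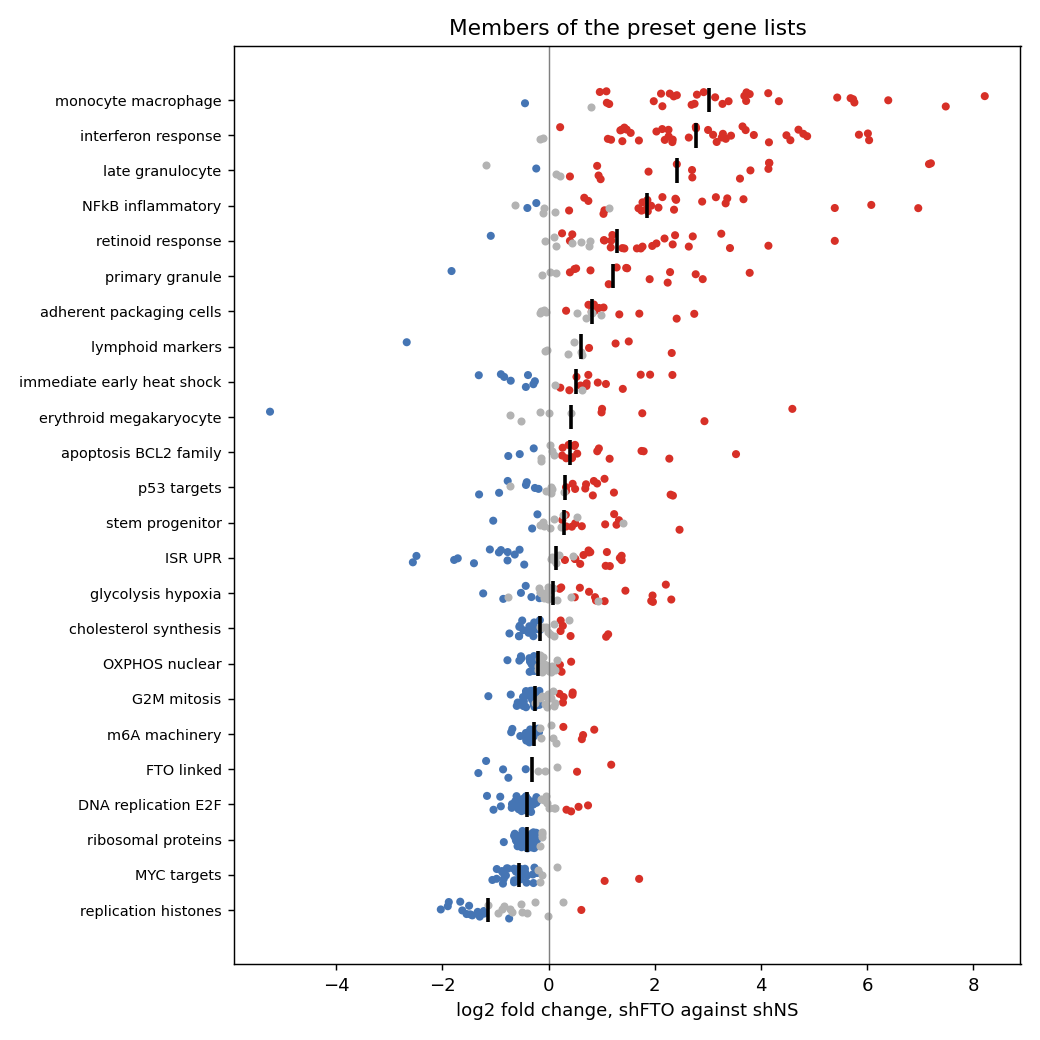
Log2 fold changes, shFTO against shNS (horizontal axis), of the measured members of the 24 lists fixed beforehand. Red and blue points passed the edgeR test as higher or lower, grey points did not, and black bars are list medians; the monocyte and interferon lists have the highest medians, 3.03 and 2.77.

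In all, 16 of 24 lists (15 with FTO left out of its own list) passed camera with the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 19. With library size as the only scaling, the interferon and monocyte lists passed with an estimated correlation (adjusted p 0.036 for each). Each of these lists did so in 1 of 13 alternative settings. The replicate block and the settings without a library leave fewer residual degrees of freedom than the 2 of the main fit. A pass with an estimated correlation was hardly possible there, so failing to pass says little about the lists. Each gene rested on 1 listed transcript and on a single hairpin label per group.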

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

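Across the alternatives, 0 of the 8503 calls passed the other way. The FTO log2 fold change stayed negative and past the threshold. It ran from -1.16 on log2(TPM + 1) to -1.38 (-1.28 to -1.38 with a library left out). Leaving out each library in turn, where the lone library of its group is assumed to vary like the other group, gave 3953 to 4064 higher and 3687 to 3758 lower genes. The deposited TPM values kept 78.0% of calls and gave 2655 lower genes, and the cause was not tested. A test against a 1.5-fold change, which asks for larger effects by construction, called 1978 higher and 506 lower genes. Camera with an estimated correlation called 0 lists. For the interferon list the estimate was 0.011, near the preset 0.01, yet camera's unadjusted p was 0.0023 against 4.2e-96. The DNA replication and late granulocyte estimates, 0.0013 and -0.037, lay below the preset, with camera p of 0.028 and 0.016 against 4.9e-07 and 1.2e-12. A higher correlation between genes is thus argued against as the cause for these lists. The form with an estimated correlation takes its p-value from the fit's 2 residual degrees of freedom, and the preset form does not. For lists with larger estimates, up to 0.98 for ribosomal proteins, how much the correlation added was not tested. With an estimated correlation, 5 lists had an unadjusted p under 0.05, and interferon and monocyte lists passed with library size only (adjusted p 0.036). Fry called 19. The replicate numbers share only a number, with a correlation of -0.0059 between deviations of libraries with the same number, over only 2 pairs; the replicate block gave 4903 higher and 4709 lower genes. The 139 named genes besides FTO were mostly picked for passing the main test. Of their 2214 values, 2178 kept their side of the threshold, 31 lost it, 5 gained it and 0 passed the other way. Camera calls with the preset correlation were lost by the lymphoid list without shNS replicate 1 (adjusted p 0.20) and with no filter (0.11), and by the glycolysis list with no filter (0.095) and the block (0.13). The histone list lost its call without shNS replicate 2 (0.065) and with the GC and length trend removed (0.094), and the respiratory list in both of these (0.053 and 0.059) and without shFTO replicate 1 (0.056). Calls were gained by the m6A list without shNS replicate 2 (0.035), with no filter (0.0046) and with the block (0.013), and by the cholesterol list with no filter (0.029) and the block (0.045). The packaging cell list gained one without shNS replicate 2 (0.012), without shFTO replicate 1 (0.010), with no filter (0.0046), with the block (0.010) and with library size only (0.048). The erythroid list passed with the filter of 1 CPM (0.015, median 0.73), and its median was -0.27 without shFTO replicate 2. The late granulocyte median was 1.42 without shFTO replicate 2 and 0.96 with no filter, against 2.42. The FTO-linked list lost its call without FTO (0.11). That setting, the removal of ribosomal RNA rows, the GC and length correction and the robust fit were chosen after the data were seen. Genes near 0.1 CPM could not be told from 0 at this depth.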

Other observations

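The lists and tests in this part were chosen after the result was seen, apart from the library-size setting, which was planned. Among 40 lysosomal genes, 37 rose and 0 fell, with a median log2 fold change of 1.3. The protease CTSB rose from 86.2 ± 1.62 to 358 ± 14.4 CPM. All 21 measured complement and chemokine genes rose, C3 from 57.0 ± 0.95 to 443 ± 0.94 CPM. Of 13 genes of class I antigen presentation, 12 rose and 1 fell, and B2M rose from 967 ± 90.2 to 3407 ± 164 CPM. Camera with an estimated correlation gave adjusted p-values of 0.055, 0.055 and 0.10 for the lysosomal, complement and class I lists. These were adjusted over the 6 added lists alone, so they cannot be set beside those of the 24 lists fixed beforehand. The lysosomal list's unadjusted camera p was 0.017, against 0.0023 for the interferon list.

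Genes for charging transfer RNA and for making serine fell. Of 20 aminoacyl-tRNA synthetases, 19 fell and 0 rose, and GARS fell from 523 ± 9.12 to 216 ± 7.30 CPM. Of 19 genes of serine synthesis and the one-carbon cycle, 16 fell and 0 rose, and SHMT2 fell from 522 ± 3.60 to 194 ± 9.38 CPM. Mitochondrial ribosomal proteins fell in 33 of 40 cases and rose in 1. With an estimated correlation the adjusted p-values were 0.098, 0.055 and 0.35, again over the 6 added lists alone.

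The rise of monocyte and macrophage genes kept a median log2 fold change of 3.0 once each library's trend with GC content and length was removed, which argues against such a trend as its whole cause. Monocytes or macrophages mixed into the shFTO cultures would dilute primary granule genes that such cells lack, but 11 such genes had a median of 0.52, with 8 rising and 1 falling, which argues against mixing as the cause for those 11 only. For the monocyte genes, and granule genes that monocytes share, mixing cannot be told apart from a change in the NB4 cells. Of 4 transcripts abundant in such cells, only 1 (CD74, with a rise of 4.20 CPM) rose by less than the median list member's 17.7 CPM, although all 4 rose by less than SIGLEC1's 40.8 CPM, so the outcome depends on the gene set beside them. An effect of the hairpin or vector other than FTO loss may also raise interferon genes, and with 1 group carrying a hairpin against FTO it cannot be told apart from FTO loss, a biological explanation the design names.

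The fall of tRNA synthetase and serine genes was not explained by a GC or length trend, since the medians were -0.67 and -0.54 after its removal. Scaling between libraries shifts all genes alike, so by arithmetic it cannot move a list relative to all tested genes. The medians lay at -0.656 and -0.559 from that of all tested genes, a relative fall that scaling leaves unchanged. These values do not settle whether the genes fell in amount per cell. With library size only the list medians were -0.61 and -0.51 (unadjusted camera p 8.3e-11 and 1.7e-10 with the preset correlation). In the main fit neither list passed camera with an estimated correlation (adjusted p 0.098 and 0.055 over the 6 added lists). Amounts of RNA per cell were not measured. The density or feeding of the cultures at harvest could also lower these genes, and it cannot be told apart from FTO loss with 2 libraries per group and no such record in the labels.

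More than 50 in 100 tested genes were called (54.7%) with 2 libraries per group. A library deposited more than once is argued against by a chi-square per gene of at least 4.62 between libraries of a group with ribosomal RNA rows left out, where sampling alone gives about 1. The small spread, a biological coefficient of variation of 5.25%, may arise because the libraries of a group share an infection or culture. That cannot be told apart from separate cultures that vary little, since the labels do not say.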
